A study of Mus musculus with 4 samples.

How the data were processed

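RNA sequencing was done on T cells taken from the spleens of 4 C57BL/6 mice, 2 given an adeno-associated virus that expresses interleukin-27 (AAV-IL-27) and 2 given a control virus (AAV-ctrl), per the labels. The virus was injected into muscle, the spleens were taken about a month later, and T cells were separated by magnetic sorting (MACS). The series title names CD8+ T cells and the cell type field says splenic T cells. Whether the sort kept or removed labelled cells is not given in the sources used here. RNA was extracted with Trizol and sequenced on DNA nanoballs. The labels name poly(A) RNA as the molecule and a library protocol built on ribosomal RNA removal, so which of these selected the RNA stays unclear, and read length is given in an ambiguous form.

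The deposited table lists 17039 genes by NCBI Gene number and symbol. The authors deposited expected counts per gene and library that need not be whole numbers, and 64.9% to 65.1% of the values in each library are whole. A second set of columns that the authors deposited was taken as FPKM, which are counts divided by gene length and library size. The file headers do not name that unit, and how the authors computed it is not given in the sources used here. It was inferred from the values: across 4743 genes, the median ratio of this value to the count moved between libraries as the ratio of the summed counts did (for AAV-IL-27 replicate 3 against replicate 1, 1.0046 and 1.0046). Columns of group averages were not used. The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12, DESeq2 1.4.5 and the genome build GRCm38.p6, without the role of each tool. Whether the counting used strand is not given in the sources used here. Where near-identical genes share reads (guanylate-binding proteins, Tgtp1 and Tgtp2, the Klra family, H2-Q genes, haemoglobins and histones), the expected counts were split by the authors' software, and values of single members are uncertain. Gene coordinates come from a RefSeq table of the same build, to which 16921 of the 17039 genes were matched by NCBI Gene number.

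The expected counts were rounded to whole numbers. Total counts were 16108507 and 16182453 in AAV-IL-27 replicates 1 and 3, and 15803526 and 15742523 in AAV-ctrl replicates 1 and 3. Genes were filtered with filterByExpr, which left 12887 of the 17039. Library factors came from TMM. The groups were compared with edgeR 4.0.16 (quasi-likelihood test, robust fit, no block) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. A log2 fold change above 0 means a higher level in AAV-IL-27. Its standard error (SE) was taken as its size divided by the square root of the test's F value. FPKM are given as mean ± SD over the 2 libraries of a group, for description only.

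Before the data were examined, 29 gene lists were fixed, and 28 had at least 5 tested members. The list of mitochondrially encoded genes had too few members and was not tested. Lists were tested with camera from limma 3.58.1 (two-sided, preset inter-gene correlation of 0.01, adjusted over the 28 lists), and again with an estimated correlation and with fry. Camera sets a list against all other genes, and fry tests a list by itself. With an estimated correlation, camera also takes its degrees of freedom from the few libraries rather than from the many genes, which raises p by itself. Each list is given with the number of members that rose, fell or did not pass over all genes tested. Adjusted over the list alone, the counts were the same unless given. The rule for naming genes was also fixed before the data were examined. It took 15 genes chosen for the biology of interleukin-27, the 10 largest rises and 10 largest falls among changed genes with a mean log2 CPM of at least 2 and groups that did not overlap (predicted genes, pseudogenes and receptor segments left out, which removed 2), and the members with the smallest p from each list, 134 genes in all. Results of some genes under the rule are not reported here. Other genes were named after their values were seen: Pdcd1, Tigit, Gzmb, Il21, Prf1, Il7r, members named because they ran against their list, and the genes of the lists chosen after the data were seen.

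The design text speaks of 4 mice, so the 2 libraries of a group come from separate animals. Counts of 2 libraries of the same group differed by more than sampling noise (chi-square per degree of freedom of 6.79 for AAV-IL-27 and 2.55 for AAV-ctrl), against 42.9 to 48.0 between groups. The fit was tested on simulated data with 2 libraries per group, drawn for 12887 genes from the means and spread of the real libraries, of which 12761 passed the filter. Changes were given to 50 genes at each fold, and to a list of genes shifted together. The fit called 48% of the genes changed 1.25-fold, 76% of those changed 1.5-fold, 86% of those changed 2-fold and 100% of those changed 4-fold. In that simulation 20 of 12531 unchanged genes tested were called, which was 10.1% of the calls and above the nominal share. Few genes were changed in the simulation, while 39% of the genes tested were called on the real data. The shares found and falsely called therefore need not hold there. The false share among the calls on the real data was not measured.

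The alternatives tried were DESeq2 size factors, upper-quartile factors and library size alone in the same edgeR fit, no filter on low counts, at least 50 counts in 2 libraries, a replicate block, a fit without the robust option, a fold change limit, DESeq2 1.42.0 with its defaults, limma-voom, limma on log2(FPKM + 1), and each library left out in turn. With a library left out, the lone library of a group was assumed to vary like the other group. Without an AAV-ctrl library, the spread thus came from the AAV-IL-27 pair, whose libraries differed more (chi-square per degree of freedom 6.79 against 2.55). A call lost that way need not rest on the control left out. Scaling libraries to the list of T cell and CD8 identity genes, and counts of list members without each library, were added after the data were seen. Alternatives planned for a file without counts were not needed. Intervals on counts are exact 95% binomial intervals and cover counting error only. Figures were drawn with matplotlib 3.10.9.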

Results

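Gene expression was measured by RNA sequencing in splenic T cells, named as CD8+ in the series title, from mice that carried a muscle-injected adeno-associated virus expressing interleukin-27 (IL-27) or a control virus. IL-27 is a cytokine built from the subunits p28 (Il27) and Ebi3, and it signals through the receptor chains Il27ra and Il6st. There were 2 libraries per group, replicates 1 and 3, each from its own mouse. Total counts ranged from 15742523 to 16182453 per library, and 12887 of 17039 genes were tested. The comparison asked which genes change in these cells in animals with IL-27 delivered from muscle.

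T cell preparations of AAV-IL-27 mice held more transcripts of interferon-inducible GTPases, antigen presentation genes, cytotoxic effector genes, co-inhibitory receptors and cell cycle genes, and fewer of genes typical of naive T cells. Neutrophil granule genes, which T cells are not known for, were also higher, and natural killer receptor genes were lower. Of the 16 lists called, 2 kept the call with an estimated correlation, interferon-inducible GTPases and cell cycle genes (adjusted p = 0.0479 each). Fry's direction test, which takes a list by itself, lost the call of 1 of the 16, B cell genes (adjusted p = 0.206). Of the 12887 genes tested, 5023 changed (39.0%), 2745 higher and 2278 lower, by edgeR's quasi-likelihood test. A rise of at least 2-fold was found for 677 genes and a fall of at least 2-fold for 289, and 209 rose and 53 fell at least 4-fold. The groups lay apart on the first principal component, which held 81.4% of the variance. All 5023 changed genes had groups that did not overlap, as did 71.5% of the tested genes, where 33.3% is the share chance gives with 2 against 2.

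The count depended on the libraries and the scaling. Without AAV-ctrl replicate 1 the test called 2635 genes, and without AAV-ctrl replicate 3 it called 2743, against 4526 and 4886 without AAV-IL-27 replicate 1 or 3. DESeq2 called 3185. Of the genes named below as changed, Adamts14, Atp5s, Bcl6, Ccr4, Cdh5, Hemgn, Il18, Itga2, Itga2b, Khdc1a, Nlrc4, S1pr5, Sdc1, Slamf6 and Slfn8 did not pass by it. With upper-quartile factors the calls split into 2362 higher and 2979 lower, and with library size alone into 2363 and 2975. Scaled to the T cell list, a choice made after seeing the data, they split into 1278 higher and 4477 lower. Among the genes named below as changed, Cd27, Cd28, Cd8a, Cdh5, Eomes, Hemgn, Itga2b and Rpl24 then did not pass. This scaling moved the median log2 fold change of all genes from -0.00528 to -0.227. By construction, a change of scaling shifts all genes nearly alike. The medians of the 28 lists therefore moved by at most 0.026 relative to the median of all genes, which is no test of the lists.

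**Figure D1:**
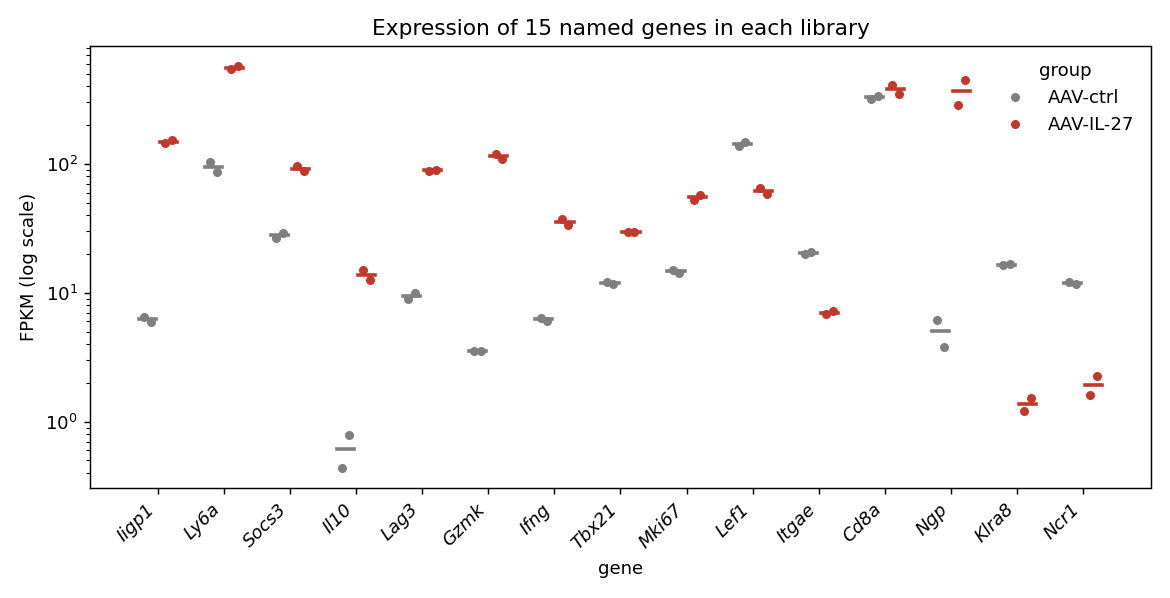
FPKM of 15 named genes on a log axis, with a point for each library and a line at the group mean of the 2 libraries, in grey for AAV-ctrl and red for AAV-IL-27. Gzmk lay at 3.55 FPKM in AAV-ctrl and 115 in AAV-IL-27, Lef1 at 142 and 61.8, and Klra8 at 16.6 and 1.38.

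Neither subunit of IL-27 was found to change in these cells. Il27 had 3.09 to 9.52 expected counts per library in both groups, too few for a test. Ebi3 (NCBI Gene 50498) stood at 5.73 FPKM in each AAV-IL-27 library and 7.37 ± 1.67 FPKM (SD, n = 2) in AAV-ctrl (log2 fold change -0.35 ± 0.18 (SE), edgeR adjusted p = 0.159). Il27ra (NCBI Gene 50931, chromosome 8, 84030286 to 84042600) fell by 0.45 ± 0.054 on the log2 scale (adjusted p = 0.000203), from 111 ± 3.16 to 77.6 ± 4.41 FPKM. Il6st fell by 0.63 ± 0.065 (adjusted p = 0.000105). Stat3, a transcription factor activated by cytokine receptors, rose by 0.67 ± 0.048 (adjusted p = 8.67e-06).

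Many genes induced by interferons rose. All 20 tested interferon-inducible GTPases, enzymes that act against intracellular microbes, rose (median log2 fold change 1.60, camera adjusted p = 1.69e-115, and adjusted p = 0.0479 with an estimated correlation). Iigp1 (NCBI Gene 60440, chromosome 18, 60373616 to 60392634) went from 6.23 ± 0.382 to 149 ± 4.26 FPKM (4.62 ± 0.067, edgeR adjusted p = 1.05e-09). Igtp rose by 2.59 ± 0.052 and Gbp10, a near-copy of other guanylate-binding protein genes and therefore uncertain, by 2.95 ± 0.061. Of 49 interferon-stimulated genes, 30 rose, 5 fell and 14 did not pass, and 35 rose and 5 fell adjusted over the list alone (median 0.54, camera adjusted p = 2.35e-13, but adjusted p = 0.301 with an estimated correlation). Ly6a, the stem cell antigen Sca-1, rose by 2.61 ± 0.088 and Irf1, a transcription factor of the interferon response, by 1.14 ± 0.051, with Zbp1 at 1.62 ± 0.049. The 5 that fell were Ifi208, Samd9l, Ddx60, Slfn5 and Slfn8, of which Slfn8 (adjusted p = 0.198) and Ddx60 (adjusted p = 0.0742) did not pass without AAV-ctrl replicate 1. Slfn8 did not pass without AAV-ctrl replicate 3 (adjusted p = 0.191) or AAV-IL-27 replicate 1 (adjusted p = 0.169) either.

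All 22 tested genes of MHC class I and its antigen processing rose (median 0.60, camera adjusted p = 4.51e-18, and adjusted p = 0.148 with an estimated correlation). Psmb8, a subunit of the immunoproteasome, rose by 0.81 ± 0.052, Nlrc5, the transactivator of MHC class I genes, by 0.81 ± 0.047, and Pdia3, a chaperone of peptide loading, by 0.90 ± 0.045. Scaled to the T cell list, 13 of the 22 rose.

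Cytotoxic effector genes were higher. Of 28 tested, 22 rose, 2 fell and 4 did not pass, and 22 rose and 3 fell adjusted over the list alone (median 0.83, camera adjusted p = 4.96e-17, and adjusted p = 0.288 with an estimated correlation). The AAV-IL-27 libraries differed in these genes, with 3 of 28 higher in replicate 3 than in replicate 1 (median log2 ratio -0.144). Their share of the counts was 0.437% in AAV-IL-27 replicate 1 and 0.356% in replicate 3, against 0.190% and 0.185% in AAV-ctrl. Gzmk, which encodes granzyme K (NCBI Gene 14945, chromosome 13, 113171630 to 113180965), went from 3.55 ± 0.00707 to 115 ± 7.32 FPKM (5.06 ± 0.10, edgeR adjusted p = 4.47e-09). Ifng rose by 2.56 ± 0.099, Tbx21, the transcription factor T-bet, by 1.36 ± 0.064, and Prf1, perforin, by 1.01 ± 0.057. Gzmb, granzyme B, rose by 4.55 ± 0.46 (adjusted p = 0.0191). It did not pass without AAV-ctrl replicate 1 or replicate 3, though its log2 fold change stayed at 4.63 and 4.48. Klrd1 and S1pr5 fell, and S1pr5 did not pass without AAV-ctrl replicate 1 (adjusted p = 0.344), AAV-IL-27 replicate 1 (adjusted p = 0.0639) or AAV-IL-27 replicate 3 (adjusted p = 0.11). In the same libraries the natural killer markers, cells that share several of these genes, fell (median -1.94).

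Co-inhibitory receptors and factors tied to T cell exhaustion were higher as well, with 13 of 23 members rising, 3 falling and 7 not passing (median 0.58, camera adjusted p = 2.32e-13, and adjusted p = 0.134 with an estimated correlation). Lag3, an inhibitory receptor (NCBI Gene 16768, chromosome 6, 124904359 to 124912434), went from 9.50 ± 0.771 to 89.0 ± 0.99 FPKM (3.28 ± 0.066, edgeR adjusted p = 4.47e-09). Tox2 rose by 4.10 ± 0.24, Pdcd1, which encodes PD-1, by 3.62 ± 0.24, Tigit by 3.58 ± 0.17 and Cd274, which encodes PD-L1, by 1.03 ± 0.056. Nt5e, Btla and Cd200 fell, the last not passing without AAV-ctrl replicate 1 (adjusted p = 0.0995) or replicate 3 (adjusted p = 0.103). Of 20 genes of STAT3 signalling and cytokine feedback, 14 rose, 2 fell and 4 did not pass (median 0.67, camera adjusted p = 2.17e-13, and adjusted p = 0.148 with an estimated correlation). Il10, an anti-inflammatory cytokine, went from 0.615 ± 0.247 to 13.8 ± 1.63 FPKM (4.53 ± 0.23, adjusted p = 1.03e-06). Il21 rose by 4.81 ± 0.48, Socs3, a feedback inhibitor of STAT3 signalling, by 1.77 ± 0.066, Prdm1, the transcription factor Blimp-1, by 2.04 ± 0.14, and Maf by 2.30 ± 0.14. Il4ra and Bcl6 fell. Bcl6 did not pass without any of the 4 libraries (adjusted p from 0.0793 without AAV-IL-27 replicate 1 to 0.279 without AAV-ctrl replicate 3, with 0.0817 and 0.0854 for the others).

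Genes of naive and central memory T cells were lower. Of 25 tested, 21 fell, 2 rose and 2 did not pass (median -0.59, camera adjusted p = 2.87e-15, and adjusted p = 0.148 with an estimated correlation). Lef1, a transcription factor of naive T cells, fell by 1.19 ± 0.065 (edgeR adjusted p = 2.22e-06), from 142 ± 8.15 to 61.8 ± 4.33 FPKM. Itgae, the integrin CD103, fell from 20.4 ± 0.53 to 7.02 ± 0.262 FPKM (adjusted p = 5.14e-07), Il7r, the interleukin-7 receptor, from 171 ± 5.03 to 69.8 ± 9.52 FPKM (adjusted p = 0.000116), and Klf2, which keeps homing receptors on, by 0.81 ± 0.046 on the log2 scale. Cd28 and Cd27 rose, but did not pass when scaled to the T cell list (adjusted p = 0.127 and 0.156). The list of memory precursor genes, which shares 14 members with other lists, went both ways, with 9 of 19 rising, 5 falling and 5 not passing (median 0.32, camera adjusted p = 8.01e-05, and adjusted p = 0.148 with an estimated correlation). Cxcr3, a chemokine receptor, rose by 1.59 ± 0.082, and Eomes, a transcription factor of memory cells, by 0.32 ± 0.052 (edgeR adjusted p = 0.00117), though not when scaled to the T cell list (adjusted p = 0.468). Il7r, Id3, Tcf7, Slamf6 and Bcl2 fell. Without AAV-ctrl replicate 1 and without AAV-ctrl replicate 3, 2 members fell, and Tcf7 (adjusted p = 0.0567 and 0.125), Slamf6 (0.129 and 0.19) and Bcl2 (0.258 and 0.0637) did not pass. Slamf6 (adjusted p = 0.0744) and Bcl2 (adjusted p = 0.128) did not pass without AAV-IL-27 replicate 1 either. Without genes held by another list, the list was not called (camera adjusted p = 0.0615).

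Cell cycle genes were higher throughout, with all 36 rising (median 1.63, camera adjusted p = 1.51e-93, and adjusted p = 0.0479 with an estimated correlation). Mki67, a marker of dividing cells (NCBI Gene 17345, chromosome 7, 135689784 to 135716450), went from 14.7 ± 0.481 to 55.1 ± 3.44 FPKM (1.97 ± 0.058, edgeR adjusted p = 5.15e-08). Top2a rose by 2.05 ± 0.056, Ccna2 by 2.10 ± 0.064 and Rrm2 by 2.09 ± 0.068. The neutrophil markers, whose precursors divide, rose in the same libraries (median 5.53).

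Energy metabolism genes were higher by smaller factors. Of 20 glycolysis genes 14 rose and none fell past the threshold by edgeR over all genes, while 14 rose and 1 fell adjusted over the list alone (median 0.39, camera adjusted p = 5.31e-07, and adjusted p = 0.148 with an estimated correlation). Pfkp rose by 1.24 ± 0.048, Gapdh by 0.94 ± 0.049 and Ldha by 0.79 ± 0.045. Of 76 genes of oxidative phosphorylation 51 rose, 1 fell and 24 did not pass, and 58 rose and 1 fell adjusted over the list alone (median 0.29, camera adjusted p = 2.34e-06, and adjusted p = 0.148 with an estimated correlation). Cox5a rose by 0.69 ± 0.057 and Sdhb by 0.58 ± 0.057. Atp5s fell, but did not pass without any of the 4 libraries (adjusted p from 0.075 without AAV-IL-27 replicate 3 to 0.242 without AAV-ctrl replicate 3, with 0.097 and 0.137 for the others). Of 81 cytosolic ribosomal protein genes 31 fell, 2 rose (Rps27l and Rpl24) and 48 did not pass (median -0.09, camera adjusted p = 0.00169, and adjusted p = 0.485 with an estimated correlation). Rps24 fell by 0.39 ± 0.041 and Rps29 by 0.40 ± 0.05. These small shifts depended on the setting. Without AAV-ctrl replicate 1, 28 oxidative phosphorylation genes rose and 11 ribosomal genes fell. Without AAV-ctrl replicate 3 these numbers were 34 and 11. Rpl24 did not pass without AAV-ctrl replicate 1 (adjusted p = 0.146) or replicate 3 (adjusted p = 0.0712). Scaled to the T cell list, 8 glycolysis genes rose and 3 fell, 4 oxidative phosphorylation genes rose and 62 ribosomal genes fell, with Rpl24 at -0.03.

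Other lists of T cell biology held members that moved both ways and were not called by camera. Among 26 cytokine receptor genes 10 rose, 8 fell and 8 did not pass (camera adjusted p = 0.168), with Il12rb1 up by 2.29 ± 0.093 and Il12rb2, the chains of the interleukin-12 receptor, up by 2.15 ± 0.10, while Il6ra fell by 0.81 ± 0.052. Among 23 chemokine receptor and homing genes 9 rose and 7 fell (camera adjusted p = 0.976), and Itgal, the integrin LFA-1 alpha chain, rose by 0.75 ± 0.057. Of the 23, 5 rose and 8 fell when scaled to the T cell list. Of 24 immediate early and stress genes 8 rose and 5 fell (camera adjusted p = 0.976, down, though the median was 0.11), with Jun up by 0.65 ± 0.05 and Egr1 down at -0.56 ± 0.049. Of these, 4 rose without AAV-ctrl replicate 1 or replicate 3, and scaled to the T cell list 4 rose and 6 fell. Of 23 apoptosis regulators 7 rose and 5 fell (camera adjusted p = 0.224), among them Bmf, a pro-apoptotic BH3 protein, at -1.39 ± 0.11, and 2 fell without AAV-ctrl replicate 1 or replicate 3. Of 6 genes of interleukin-17 and type 2 cytokines, Maf rose and Ccr4 fell (camera adjusted p = 0.546), and Ccr4 did not pass without AAV-ctrl replicate 1 (adjusted p = 0.165) or AAV-IL-27 replicate 3 (adjusted p = 0.0863), while 3 of the 6 rose and 2 fell without AAV-IL-27 replicate 1. Of 12 replication-dependent histone genes 2 rose and 5 fell, and 3 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.976, down, with a median of -0.42 and a mean of 0.10). The number of histone genes that fell was 2 without AAV-IL-27 replicate 1, 3 without AAV-IL-27 replicate 3, 2 without AAV-ctrl replicate 1 and 1 without AAV-ctrl replicate 3.

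**Figure D2:**
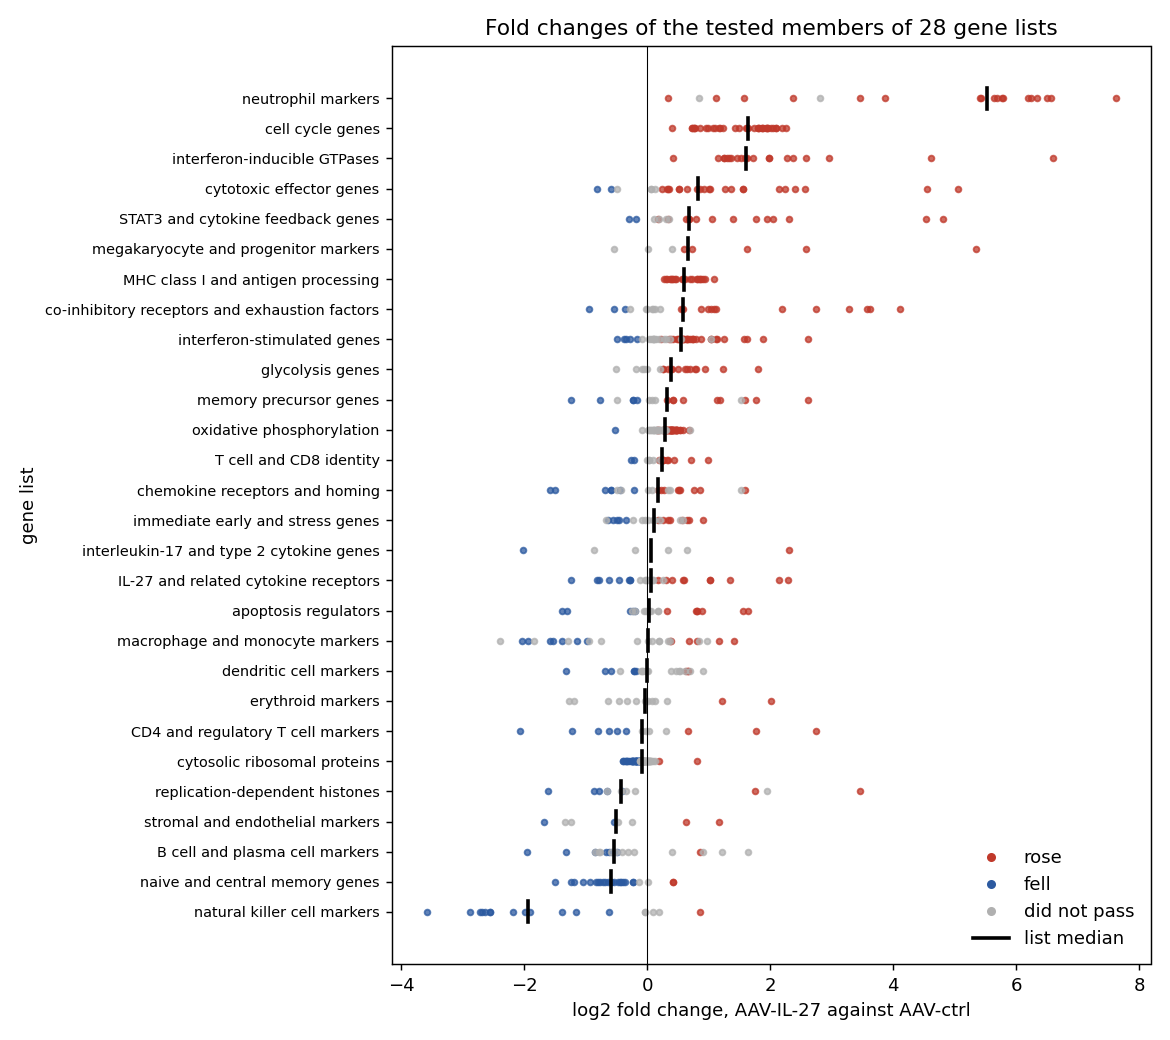
Log2 fold changes of the tested members of 28 gene lists, AAV-IL-27 against AAV-ctrl, with a point for each gene (red for genes that rose, blue for genes that fell, grey for genes that did not pass) and a black line at each list's median. The neutrophil list has the highest median, at 5.53, and the natural killer list the lowest, at -1.94.

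Among T cell markers, Cd8a stood at 379 ± 41.6 FPKM in AAV-IL-27 and 328 ± 10 in AAV-ctrl (0.26 ± 0.074, edgeR adjusted p = 0.0307), and did not pass without AAV-ctrl replicate 1 (adjusted p = 0.192) or replicate 3 (adjusted p = 0.109), nor with upper-quartile factors (adjusted p = 0.0551), library size alone (adjusted p = 0.0605) or scaling to the T cell list (adjusted p = 0.832). Cd8b1 was at -0.01 ± 0.064 (adjusted p = 0.917) and Cd4 at -0.03 ± 0.099 (adjusted p = 0.853), and their signs turned without AAV-IL-27 replicate 3 (Cd8b1, 0.0825), AAV-ctrl replicate 3 (Cd8b1, 0.00231) and AAV-IL-27 replicate 1 (Cd4, 0.107). Of 17 T cell and CD8 identity genes 10 rose, 2 fell, Thy1 among them, and 5 did not pass (median 0.23, camera adjusted p = 0.0535). Lat rose by 0.70 ± 0.078 and Cd7 by 0.99 ± 0.10. The list was called up without AAV-IL-27 replicate 3 (camera adjusted p = 5.7e-05) and without AAV-ctrl replicate 3 (camera adjusted p = 0.0398). Thy1 did not pass without AAV-ctrl replicate 1 (adjusted p = 0.107) or replicate 3 (adjusted p = 0.0903). Fewer of the 17 rose without AAV-ctrl replicate 1 or AAV-ctrl replicate 3. Scaled to the T cell list itself, 2 rose and 2 fell. By construction that scaling holds the list still (median 0.00985), so it tests neither the list nor Cd8a, one of its members. Of 13 CD4 and regulatory T cell markers 3 rose (Nrp1, Ctla4 and Ikzf2), 6 fell and 4 did not pass (camera adjusted p = 0.604, up, with a median of -0.08). Ctla4, an inhibitory receptor, rose by 2.75 ± 0.16 and Gpr83 fell by 2.08 ± 0.28. Without AAV-IL-27 replicate 1, 3 of the 13 fell, and without AAV-ctrl replicate 1 or replicate 3, 2 fell. Ikzf2 did not pass without AAV-ctrl replicate 1 (adjusted p = 0.0646).

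Neutrophil markers, granule genes among them, were far higher in AAV-IL-27. Of 20 tested, 18 rose and 2 did not pass, and 19 rose adjusted over the list alone (median 5.53, camera adjusted p = 9.16e-14, and adjusted p = 0.382 with an estimated correlation). Their share of the counts was 0.129% ± 0.0448 (SD, n = 2) against 0.00617% ± 0.000863 in AAV-ctrl. Ngp, a granule protein (NCBI Gene 18054, chromosome 9, 110419808 to 110423012), went from 5.01 ± 1.67 to 368 ± 116 FPKM (6.25 ± 0.49, edgeR adjusted p = 0.0114). Ltf, lactoferrin, rose by 6.57 ± 0.51, Lcn2 by 6.20 ± 0.55, Camp by 6.51 ± 0.75 and S100a8, a subunit of calprotectin, by 5.77 ± 0.59. The test called 10 members without AAV-ctrl replicate 1 and 7 without AAV-ctrl replicate 3, where 1 control library was left. Ngp (adjusted p = 0.0695 and 0.0727), Ltf (0.0705 and 0.0706), Lcn2 (0.0795 and 0.083), Camp (0.118 and 0.124) and S100a8 (0.125 and 0.119) then did not pass. Their log2 fold changes stayed high, at 6.63 and 5.94 for Ngp, 6.88 and 6.32 for Ltf, 6.47 and 5.97 for Lcn2, 7.34 and 5.99 for Camp, and 5.58 and 5.98 for S100a8. By limma-voom on all 4 libraries Ltf (adjusted p = 0.0523), Lcn2 (0.0752), S100a8 (0.0864) and Camp (0.122) did not pass either. Ly6g and Prtn3 had 1 count in AAV-ctrl and 100 and 244 in AAV-IL-27, ratios of 101 (95% interval 17.7 to 4030) and 247 (43.9 to 9790). With these 2 genes at the lower end of their interval the list's median was 5.41. The 2 AAV-IL-27 libraries differed in these genes, with replicate 3 above replicate 1 for 18 of 18 abundant members (median log2 ratio 0.81), while the T cell list went the other way (-0.19).

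Natural killer cell markers were lower. Of 18 tested, 13 fell, 1 rose (Gzma, which is also on the cytotoxic list) and 4 did not pass (median -1.94, camera adjusted p = 1.7e-13, and adjusted p = 0.134 with an estimated correlation). Klra8, a lectin-like receptor (NCBI Gene 16639, chromosome 6, 130115226 to 130129898), fell by 3.59 ± 0.17 (edgeR adjusted p = 7.01e-07), Klrb1c, which encodes NK1.1, by 2.89 ± 0.12, and Ncr1, which encodes NKp46, by 2.56 ± 0.17. Klra genes are near-copies, so which of them a fragment came from is uncertain.

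Transcripts of B cells were found in all libraries and were lower in AAV-IL-27, with 7 of 20 markers falling, 1 rising (Sdc1) and 12 not passing (median -0.54, camera adjusted p = 0.00292, and adjusted p = 0.74 with an estimated correlation). Their share of the counts was 0.426% ± 0.12 against 0.595% ± 0.0359 in AAV-ctrl, with 0.342% in AAV-IL-27 replicate 1 and 0.511% in replicate 3, and Fcer2a fell by 1.96 ± 0.21. Replicate 3 lay above replicate 1 for 19 of 19 abundant members (median log2 ratio 0.46), as for the neutrophil list. The number that fell was 13 without AAV-IL-27 replicate 1, 15 without AAV-IL-27 replicate 3, 4 without AAV-ctrl replicate 1 or replicate 3, 13 without the robust option and 15 when scaled to the T cell list. The number that rose was 4 without AAV-IL-27 replicate 1, 3 without the robust option and 2 with that scaling. Sdc1, which marks plasma cells, did not pass without AAV-IL-27 replicate 3 (adjusted p = 0.132), AAV-ctrl replicate 1 (adjusted p = 0.178) or AAV-ctrl replicate 3 (adjusted p = 0.132). Of 8 megakaryocyte and progenitor markers 5 rose and 3 did not pass (median 0.66, camera adjusted p = 0.00023, and adjusted p = 0.175 with an estimated correlation), among them Mcpt8 (5.34 ± 0.17), Cpa3 (2.58 ± 0.20), Gata2 (1.62 ± 0.20) and Ms4a2 (0.73 ± 0.14), genes known from basophils and mast cells. Itga2b, the fifth, did not pass without any of the 4 libraries (adjusted p = 0.0855, 0.0883, 0.122 and 0.264).

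Further markers of other cell types went both ways. Of 27 macrophage and monocyte markers 6 rose, 7 fell and 14 did not pass (camera adjusted p = 0.399, down, with a median of 0.01 and a mean of -0.38). Cd163 fell by 1.94 ± 0.24 and C1qa by 1.38 ± 0.22, while Lilrb4a rose by 1.17 ± 0.086. The list was called without AAV-ctrl replicate 1 (camera adjusted p = 0.0468) and without AAV-ctrl replicate 3 (camera adjusted p = 6.07e-06), where 2 and 3 members rose and 8 and 9 fell, and 11 fell when scaled to the T cell list or without the robust option. Of 23 dendritic cell markers 3 rose (Bst2, Irf8 and Zbtb46) and 6 fell (camera adjusted p = 0.976, down, with a median of 0.00127 and a mean of 0.0914), with Cd209a at -1.33 ± 0.12. The number that rose was 6 without AAV-IL-27 replicate 1 and 8 without AAV-IL-27 replicate 3, and 2 fell without AAV-ctrl replicate 1. The counts were 6 and 9 when scaled to the T cell list, and 7 rose without the robust option. Of 13 erythroid markers Gata1 and Hemgn rose, and 1 rose adjusted over the list alone (camera adjusted p = 0.976). Of the 13, 1 rose and 2 fell without AAV-IL-27 replicate 3 and when scaled to the T cell list. Hemgn did not pass without any of the 4 libraries (adjusted p from 0.0949 without AAV-IL-27 replicate 3 to 0.25 without AAV-ctrl replicate 3, with 0.111 and 0.143 for the others). Of 8 stromal and endothelial markers Kdr and Cdh5 rose and Pecam1 and Stab2 fell (camera adjusted p = 0.399), and 1 rose and 4 fell when scaled to the T cell list. Without AAV-ctrl replicate 1 or AAV-IL-27 replicate 1, Cdh5 (adjusted p = 0.125 and 0.054) and Stab2 (adjusted p = 0.214 and 0.0699) did not pass.

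**Figure D3:**
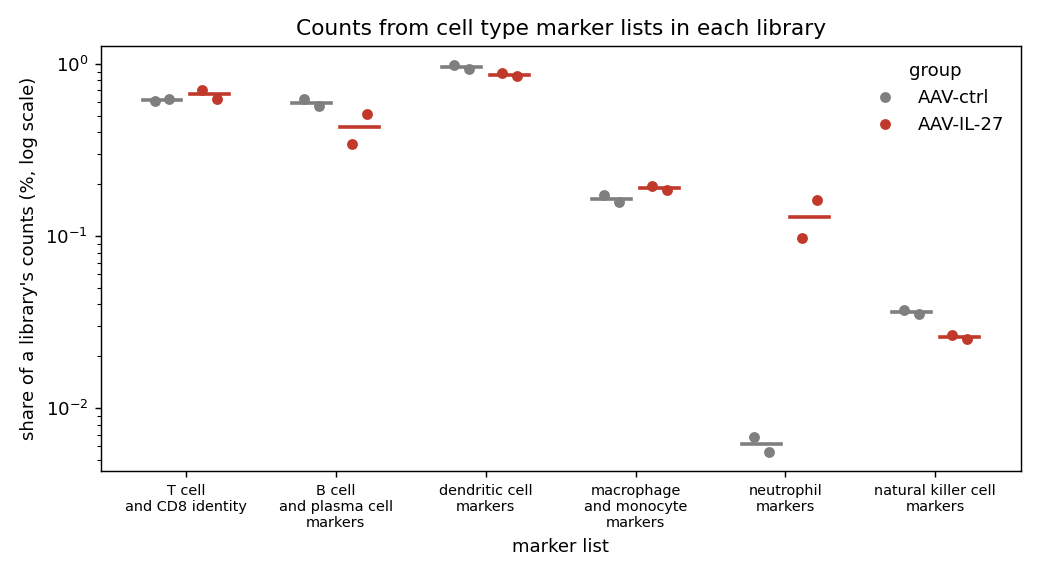
Share of each library's counts, in percent on a log axis, taken by 6 lists of cell type markers, with a point for each library and a line at the group mean. The neutrophil list took 0.00617% of the counts in AAV-ctrl and 0.129% in AAV-IL-27, and the T cell list 0.616% and 0.663%.

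Of the 10 largest rises, taken without 2 predicted genes of which 1 is on the list of interferon-inducible GTPases, 7 were of granulocyte genes (Ltf, Camp, Ngp, Lcn2, Fcnb, Elane and S100a8). The 10 also held Prss34, a protease of mast cells and basophils, which rose by 5.88 ± 0.22, Insrr and Faxc. Faxc rose by 6.60 ± 0.34 (edgeR adjusted p = 1.83e-05), with 1 and 9 counts in the AAV-ctrl libraries and 528 and 454 in the AAV-IL-27 libraries. Insrr had 2 counts in AAV-ctrl and 316 in AAV-IL-27, a ratio of 160 (95% interval 43.9 to 1330), and Fcnb 2 and 261, a ratio of 132 (36.2 to 1100). The 10 largest falls held 5 receptor genes of the Klra family (Klra8, Klra9, Klra1, Klra4 and Klra7), Klrb1c and Ncr1, and the near-copies among them are uncertain. They also held Prss12, a serine protease, at -3.25 ± 0.24 and Trat1, an adaptor of the T cell receptor, at -2.43 ± 0.14. Fcna, a ficolin of splenic macrophages, fell by 2.87 ± 0.57 (adjusted p = 0.027), but did not pass without AAV-IL-27 replicate 1 (adjusted p = 0.202) or replicate 3 (adjusted p = 0.199), by limma-voom (adjusted p = 0.131) or with no filter (adjusted p = 0.097).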

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

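Scaling to the T cell list was chosen after the data were seen, as were some of the named genes, and the other settings before. Of 191 named genes, 179 passed the threshold and 135 of these kept direction and call in every setting that gave a value. Calls were lost most often without AAV-ctrl replicate 1 (33 genes) or replicate 3 (27), while 16 were lost with DESeq2, 12 with T cell scaling, 5 with limma-voom and 7 with a replicate block, and none with DESeq2 size factors in edgeR or at least 50 counts. The 5023 changed genes became 3185 with DESeq2, 1212 of them lower, and 3110 of these were among the 5023 with the same sign. A limit of 2-fold left 966 (677 higher, 289 lower). With a library left out in turn the count ran from 2635 to 4886, with 1646 to 2632 higher and 989 to 2254 lower, where fewer libraries were tested. Scaled to the T cell list, 1278 were higher and 4477 lower. The numbers 1 and 3 are given to both groups, but nothing in the labels pairs the mice, and the deviations of same-numbered libraries were not correlated across genes (r = -0.000711). A replicate block called 4971 genes, 4801 of them among the 5023 with the same sign. It changed no list's call, and among the lists that were not called it turned chemokine receptors and homing (adjusted p = 0.902), immediate early genes (0.835) and histones (0.973). Camera called 16 lists, and 16 to 18 without a library. With an estimated correlation 2 lists kept the call. The adjusted p was then 0.301 for interferon-stimulated genes, 0.148 for MHC class I, STAT3 feedback, naive, memory precursor, glycolysis and oxidative phosphorylation genes, 0.134 for co-inhibitory and natural killer genes, 0.288 for cytotoxic, 0.74 for B cell, 0.382 for neutrophil, 0.175 for megakaryocyte and 0.485 for ribosomal genes. By construction this test lets the genes of a list vary together. Natural killer and glycolysis genes lost the call with estimated correlations of -0.026 and -0.05, so there the loss does not come from genes that vary together. It comes from the degrees of freedom, which camera then takes from the few libraries and not from the genes. This holds for every list, so a lost call does not by itself show that a list's genes vary together. Fry's direction test gave 0.00628 for apoptosis, 0.0323 for interleukin-17 and type 2, 0.0129 for CD4 and 0.206 for B cell genes, and turned immediate early (0.463), dendritic (0.693), erythroid (0.532) and histone genes (0.238). Fry's mixed test, which has no direction, called all 28 lists. It takes a list by itself, and 39% of all tested genes changed, so a call by it does not set a list apart. Its adjusted p was 0.00408 for cytokine receptors and for interleukin-17 and type 2 genes, 0.00537 for chemokine receptors, 0.00302 for immediate early and 0.00195 for apoptosis genes. It was 0.0246 for T cell identity, 0.00485 for CD4 and for stromal, 0.023 for macrophage, 0.011 for dendritic, 0.0236 for erythroid and 0.00674 for histone genes. Without genes held by another list, memory precursor genes lost the call (0.0615), cytokine receptors gained it (0.0415) and CD4 genes turned (0.759). With no filter, T cell identity was called (0.00817), megakaryocyte markers were not (0.0875), and immediate early (0.529), interleukin-17 (0.664), CD4 (0.658), dendritic (0.922) and erythroid genes (0.58) turned. The lists for chemokine receptors, erythroid genes and histones, none called, turned with upper-quartile factors (0.988, 0.929 and 0.929), library size alone (0.986, 0.926 and 0.926), at least 50 counts (0.995, 0.806 and 0.806) and T cell scaling (0.926, 0.63 and 0.537), the last of which also turned immediate early (0.914) and dendritic genes (0.897). Leaving out a library gave 0.545 to 0.827 for chemokine receptors, 0.552 to 0.947 for immediate early, 5.7e-05 to 0.193 for T cell identity, 6.07e-06 to 0.925 for macrophage, 0.181 to 0.944 for dendritic, 0.715 to 0.923 for erythroid and 0.739 to 0.863 for histone genes. It moved the log2 fold change of Cd8b1 from -0.11 to 0.0825 and of Cd4 from -0.176 to 0.107. The gene Osbpl5 (0.01) turned with upper-quartile factors (-0.0437), library size alone (-0.043), limma on log2(FPKM + 1) (-0.0376) and T cell scaling (-0.219), and ran from -0.0741 to 0.0842 without a library. Rpl24 turned with T cell scaling (-0.0295). The causes of these turns were not tested. Low counts limit the folds of Ly6g, Prtn3, Fcnb and Insrr, which had 1 or 2 counts in AAV-ctrl.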

Other observations

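The 8 gene lists, the tests on neutrophil and cell cycle genes and the test of dilution were chosen after the results were seen, while the bounds for the further natural killer list were written before its values were seen. The p-values of these 8 lists are therefore for description only and give no independent support. Many members of the lists of proteasome subunits, endoplasmic reticulum chaperones and aminoacyl-tRNA synthetases were higher in AAV-IL-27. All 14 core proteasome subunits rose (median log2 fold change 0.46, camera adjusted p = 4.66e-08, and adjusted p = 0.175 with an estimated correlation), with Psma4 at 0.70 ± 0.051 (SE). Of 16 chaperones of the endoplasmic reticulum 13 rose and 3 did not pass (median 0.38, adjusted p = 8.23e-05, and 0.429 with an estimated correlation), among them Hspa5, the chaperone BiP, at 0.67 ± 0.053 and Sdf2l1 at 1.16 ± 0.10. Of 19 cytosolic aminoacyl-tRNA synthetases 11 rose and 8 did not pass (median 0.20, adjusted p = 0.000354, and 0.175 with an estimated correlation). Wars, which charges tryptophan and is induced by interferon-gamma, rose by 1.38 ± 0.051 and Aars by 0.85 ± 0.051. Fewer chaperones and synthetases passed without AAV-ctrl replicate 1 or replicate 3, but their medians hardly moved. The medians were 0.376 and 0.39 for the chaperones and 0.191 and 0.195 for the synthetases. Counts on these lists depended on the scaling. Scaled to the T cell list, 6 proteasome subunits, 7 chaperones and 2 synthetases rose, and the median of the synthetases turned to -0.02. Enzymes of cholesterol synthesis went both ways, with 8 of 20 rising, 2 falling and 10 not passing (adjusted p = 0.88, up, with a median of -0.04), and 2 rose without AAV-ctrl replicate 1 or replicate 3. With the T cell scaling 2 rose and 8 fell (median -0.26).

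Genes of inflammasomes, of serpins, and of S100 proteins, annexins, galectins and vimentin were higher too. Of 13 inflammasome and pyroptosis genes 9 rose, 2 fell (Nlrc4 and Il18) and 2 did not pass (median 0.44, camera adjusted p = 0.000629, and 0.175 with an estimated correlation). Casp1 rose by 1.42 ± 0.089 and Casp4 by 1.66 ± 0.091. Without AAV-ctrl replicate 1 or AAV-IL-27 replicate 1 neither Nlrc4 (adjusted p = 0.181 and 0.0884) nor Il18 (adjusted p = 0.332 and 0.095) passed, nor did Nlrc4 without AAV-ctrl replicate 3 (0.0551) or Il18 without AAV-IL-27 replicate 3 (0.0664), nor either by DESeq2 (0.14 and 0.121). Scaled to the T cell list 6 of the 13 rose and 3 fell. Of 6 serpins of clades a3 and b 4 rose and 2 did not pass, Serpinb1a (-0.33 ± 0.277) and Serpinb6a (-0.16 ± 0.0928) (median 1.43, adjusted p = 1.67e-14, and 0.118 with an estimated correlation), Serpina3f by 4.06 ± 0.14 and its close relative Serpina3g by 2.39 ± 0.064. The serpins that fell were 2 of 6 when scaled to the T cell list, 1 of 7 without AAV-IL-27 replicate 3, and 1 of 7 with no filter, where the list had an adjusted p of 0.0257. Of 12 genes, those of S100 proteins, annexins and galectins and Vim, which encodes vimentin, 10 rose and 2 did not pass (median 0.86, adjusted p = 4.66e-08, and 0.175 with an estimated correlation), with S100a6 at 2.10 ± 0.19, Anxa1 at 1.77 ± 0.17 and Lgals3 at 1.61 ± 0.094. Myeloid cells also express many genes of these 3 lists, and the neutrophil markers rose in the same libraries (median 5.53).

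Neutrophil markers, granule genes among them, were higher in AAV-IL-27, and granulocyte-lineage cells in the magnetic preparation are a candidate source. Between the AAV-IL-27 libraries, the list's median log2 ratio of replicate 3 to replicate 1 was 0.811 (quartiles 0.653 to 0.951), apart from the T cell list (-0.189, quartiles -0.243 to -0.116), and B cell markers moved the same way (0.46, quartiles 0.399 to 0.556), but ribosomal protein genes, which T cells express, lay apart from the T cell list too (0.0253, quartiles -0.00671 to 0.0659), so granulocyte-lineage cells and expression in the T cells cannot be told apart by this ratio. A lower share of T cells that raised every other cell type alike is argued against by the natural killer list, whose median was -1.94 (upper quartile -0.188), and by B cell markers at -0.539 (upper quartile -0.0599). S100a9, Ngp and S100a8, the most abundant of the list's 20 tested genes, none of which is on another list, reached 429, 368 and 268 FPKM, and a sort for CD8 would be meant to remove the cells that make them. Whether IL-27 raised the number of such cells in the spleen, or the sorts differed, was not tested.

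Natural killer receptor genes were lower in AAV-IL-27. Dilution of all cells by others is argued against by the T cell list, whose median log2 fold change was 0.234 (quartiles 0.0338 to 0.325). A further list of natural killer cell genes was meant to part fewer natural killer cells (a median of -1 or lower) from lower receptor expression in T cells alone (a median above -0.5). Its 5 tested genes had a median of -0.461, just above the higher bound, but with quartiles of -0.834 and 0.00712 this lay within their spread of it: Adamts14 (-0.46), Itga2 (-0.83) and Khdc1a (-2.31) fell, each losing the call without AAV-ctrl replicate 1 (adjusted p = 0.261, 0.151 and 0.207, at -0.37, -0.87 and -2.31) and replicate 3 (0.106, 0.181 and 0.202, at -0.55, -0.80 and -2.30), Adamts14 and Khdc1a without AAV-IL-27 replicate 1 (0.158 and 0.132, at -0.27 and -1.33) and Itga2 without AAV-IL-27 replicate 3 (0.111, at -0.48), and all 3 by DESeq2 (0.173, 0.118 and 0.13), while Osbpl5 and Clnk did not pass. Fewer natural killer cells and lower receptor expression in T cells therefore cannot be told apart with so few genes, and an effect of IL-27 on either stays open and untested.

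Cell cycle genes were higher in AAV-IL-27. Dividing granulocyte precursors might carry the rise in a fixed proportion to the neutrophil transcripts. The excess over the controls would then differ between the AAV-IL-27 libraries as that of the neutrophil list did. That list's median log2 ratio of replicate 3 to replicate 1 was 0.887 (quartiles 0.679 to 1.10), but that of the cell cycle list was 0.0192 (quartiles -0.0734 to 0.0908). Under that proportion, this argues against such precursors as the whole source in these mice. The quartiles span genes, and with 1 mouse on each side the ratio cannot measure how mice vary. With libraries scaled to the T cell list the median log2 fold change was still 1.41 (quartiles 0.83 to 1.71). By construction that scaling shifts all genes nearly alike. The value therefore shows only that the rise was larger than the shift, and is no independent test of the list. On the plain ratio the list also lay apart from the T cell list (0.0111, quartiles -0.0435 to 0.0538, against -0.189, quartiles -0.243 to -0.116), as ribosomal genes did, so the ratio does not tie the rise to the T cells either. Division of the T cells themselves, or of another cell type at an equal share in both libraries, stays open and was not tested.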
